A study of Caulobacter vibrioides NA1000 with 4 samples.

How the data were processed

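ChIP-seq lists from 4 libraries of Caulobacter vibrioides NA1000 were used, 1 per group: LexA, HigA and TipR from untreated cells and TipR from cells with nalidixic acid (20 µg/ml, 3 h). Per the labels' protocols, cells grown in peptone yeast extract were cross-linked with formaldehyde, the chromatin was sonicated and precipitated with polyclonal antibodies, and the recovered DNA was sequenced. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.9 and SAMtools 0.1.18. How probes were counted and selected, and the genome build, were not given in the sources used here, and no control library was used here.

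The 7 files list probes of 50 bp. Per the file headers, the authors deposited the reads of a probe as a percent of the library's reads. The authors also deposited a score per probe, named a Z-score. It was exactly linear in the percent values for LexA and both TipR libraries, so a line through them returned the mean and SD that the authors used, and it was 0 in every HigA row, where no library mean could be had. The authors' other deposited column, the signed distance from a probe to the gene start, is positive upstream. It was used as deposited in place of a distance recomputed from the gene coordinates, which changed medians by at most 1 bp. Read totals were not given and none were derived from the percent values, so the depth set no interval here. The LexA list ends at a score of 9.71, and the TipR lists end at nearly the same score, 2.01 without and 2.05 with the drug, which stands for 0.00472% and 0.00599% of reads. The level at which the HigA list ends has no score, and the rule of selection was not given, so list lengths were not read as amounts of binding. The LexA file and the annotated files hold 1 probe per gene, and for HigA and TipR further files hold probes without a gene. Probes listed in both files of a library were used once.

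Probes within 200 bp were joined into regions, and a region took the value of its highest probe. Regions of different lists were shared if they overlapped by at least 1 bp after widening by 100 bp on each side. The number shared was set beside 10000 random circular shifts. Local shifts by 2 to 30 kb, which keep regional density, were added after the lists had been examined. The chromosome length was taken as the largest coordinate in the files, 4039689. Shares of regions have exact Clopper-Pearson 95% intervals. Shift shares describe these libraries and are not p-values between conditions. The region and shift steps were tested on simulated lists of 100 and 220 regions, where 20 of 20 planted overlaps were found.

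Gene names came from a RefSeq gene table of assembly ASM2200v1, used for names and gene order only. Of 462 genes over all lists 455 were in it, and 99 had a symbol. Lists of SOS and DNA repair, toxin-antitoxin, efflux, cell cycle and division, and heat shock and protease genes were fixed before the data were examined and matched by symbol, ignoring hyphens, in 20 comparisons of 5 lists and 4 libraries. The heat shock list had 0 members in each library, and the cell cycle list 1 each for LexA, HigA (ftsK) and TipR (ccrM) and 2 with the drug (ccrM, ftsL). Lists defined by product descriptions were not applied, since the table gives no products. The plan set gene lists beside circular shifts. As the build was not named, all 3885 rotations of the order of 3886 protein-coding genes were used in their place, and gene starts were not set beside shifts. A search for the SOS box was not run because no genome sequence was used here.

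Named genes follow a rule fixed before the data were examined: the 12 highest regions of each list, each region shared by LexA and HigA or by both TipR libraries, and each listed member of the SOS, toxin-antitoxin and efflux lists. The mraZ, ftsK, ftsL and ccrM genes are members of the cell cycle list, and CCNA_02719 and the regions with no gene in the untreated TipR list fall among its 12 highest. Alternatives were other thresholds, joining distances, widths, windows and gene-based sharing. Thresholds of 2 times the lowest value and of the lowest LexA score were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.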

Results

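Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in Caulobacter vibrioides (crescentus) NA1000, an aquatic alphaproteobacterium with a single circular chromosome. There were 4 libraries, 1 per group. LexA, the repressor of the SOS response to DNA damage, HigA, the antitoxin of the HigBA toxin-antitoxin pair, and TipR, a TetR-type repressor, were each precipitated from untreated cells, and TipR also from cells given nalidixic acid, a gyrase inhibitor, at 20 µg/ml for 3 h. Each list held 50 bp probes with the percent of the library's reads in each. No total read number came with the values and none was derived from them, so no probe value was given an interval. With 1 library per group no difference between libraries had a replicate check. Positions are those of the deposited files, whose genome build was not given in the sources used here.

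LexA was bound upstream of DNA repair genes and of several toxin-antitoxin operons. Its list held 74 probes, each with a gene of its own, which joined into 47 regions and ranged from 0.0184% to 0.773% of reads. The highest probe, at 152651 to 152700, lay 75 bp upstream of chlI (CCNA_00139) and reached 277 times the mean that the authors' score implies for this library. CCNA_03633 followed at 0.341%. The region at 2152351 to 2152600 took in sidA, an SOS-induced inhibitor of cell division, at 0.326%, with dnaE, which encodes a DNA polymerase III catalytic subunit, at 0.163% and CCNA_02005 at 0.178%. The region of CCNA_01125 and CCNA_01126 peaked at 0.317%.

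The remaining 8 of the 12 highest LexA regions began with CCNA_00697 at 0.233% and CCNA_02355 at 0.193%. CCNA_02876, in a region with CCNA_02877, stood at 0.158% and CCNA_01391 at 0.138%. The gene mmcA reached 0.131%, and bapE, an SOS-induced endonuclease gene, 0.130% in a region with CCNA_00662. The higBA region ranked 11 of the 47 at 0.128%, ahead of CCNA_01535 at 0.125%.

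Of 25 fixed-list SOS and DNA repair genes found by symbol in the gene table, 9 were in the LexA list. Besides sidA and bapE these were ruvC at 0.115% and ruvA at 0.0289%, which encode parts of the Holliday junction resolvasome, imuA of the mutagenic polymerase cassette at 0.110%, recA, the recombinase that triggers LexA self-cleavage, at 0.0936%, lexA itself at 0.0779%, mmcB at 0.0627% and the helicase gene uvrD at 0.0400%. The mean over 3885 rotations of the gene order was 0.455 genes, the highest was 8, and 0 rotations gave as many as 9. The lexA probe lay 36 bp and the recA probe 88 bp upstream of the gene start.

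Toxin-antitoxin genes were likewise listed for LexA, 9 of the 18 fixed-list genes found by symbol in the gene table. Beside higB at 0.128% and higA at 0.0627% these were socB at 0.0883% and socA at 0.0734%, of a toxin-antitoxin pair acting on the replication clamp, parD2 at 0.0447%, parE2 at 0.0437%, relB-3 at 0.0342%, relE3 at 0.0207% and parD3 at 0.0205%. The rotations gave a mean of 0.327 and at most 7, and 0 of them gave as many as 9. In the 23 LexA regions with the highest values, 3 toxin-antitoxin genes of the fixed list were left, as many as in 0.309% of the rotations. These regions also held 6 genes of the SOS and DNA repair list, as many as in 1 of 3885 rotations. The pair relB-4 and relE4, outside the fixed list, lay there too and was not counted. Neighbouring genes of an operon shared regions, so that the 9 genes of each list were not 9 separate sites. The cell cycle and division list had 1 of 40 members in the LexA list, mraZ at 0.0918%, and 50.5% of the rotations gave as many.

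HigA gave its highest value at its own operon. The list held 1173 probes in 443 regions, 203 of the probes with a gene, from 0.00187% to 0.0198% of reads. The median region value was 0.00196%. It lay under the means that the score implies for the other libraries, 0.00279% for LexA and 0.00245% for TipR without and with the drug. No HigA mean could be had, so whether the weak regions exceeded it was not known. The higBA region, at 3281101 to 3281950, peaked at 0.0198%, 10.6 times the lowest value of the list. CCNA_03436 followed at 0.00822%, CCNA_03863 and CCNA_03864 at 0.00594%, CCNA_03052 at 0.00557%, CCNA_03333 at 0.00541% and a region with no gene at 1271601 to 1272100 at 0.00450%. A second region with no gene, at 1700001 to 1700300, reached 0.00306%. The region of cheY and mcpK reached 0.00296% and CCNA_00076 0.00281%. Completing the 12 highest were gidA at 0.00261%, a region with no gene at 3468151 to 3468450 at 0.00259% and CCNA_00163 at 0.00258%. These are values of whole regions. In those of CCNA_03052, CCNA_03333, gidA and CCNA_00163 the highest probe was listed without a gene. The probes listed for these genes had 0.00378%, 0.00247%, 0.00211% and 0.00219%, in that order. In all, 9 regions reached 1.5 times the lowest value of the list, and 93.7% of the 443 lay within 25% of the coordinate span of either end of the coordinates.

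Few members of the gene lists were in the HigA list. The SOS and DNA repair list had 3, ruvC, ruvA and mutS, each at 0.00194% to 0.00198%, which 14.3% of the rotations matched. The toxin-antitoxin list had 2, higA and higB, matched by 25.4% of the rotations.

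**Figure D1:**
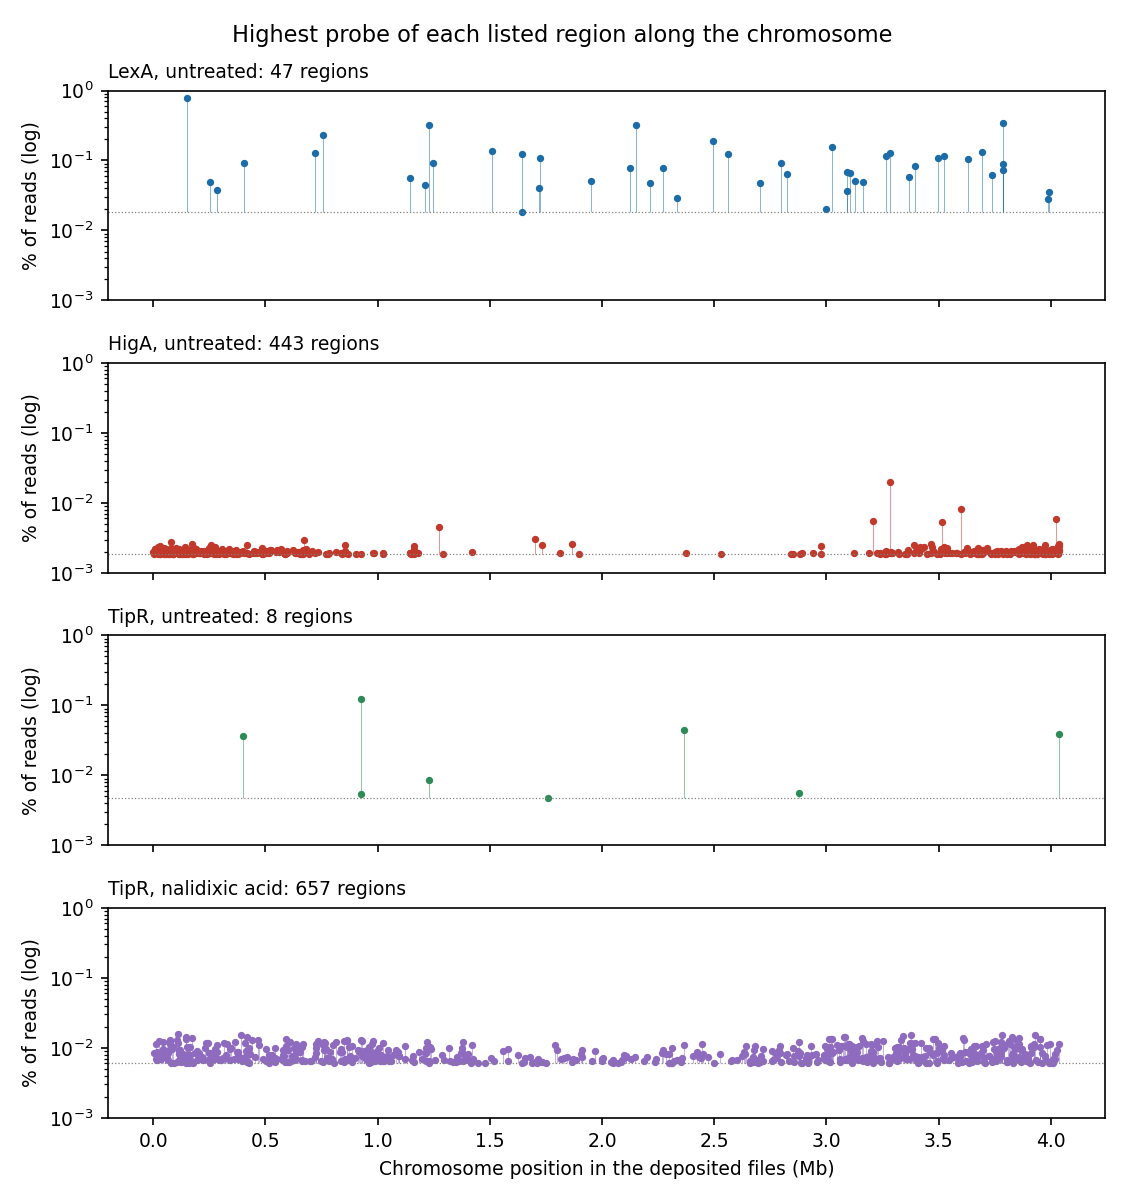
Percent of reads at the highest probe of each listed region (log axis) against its position in Mb for the 4 libraries; points are regions and the dotted line is the lowest listed value of that library. LexA values run up to 0.773%, the higBA region stands above the other HigA regions at 0.0198%, and the TipR values after nalidixic acid stay at or below 0.0157%.

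The series asks whether the binding sites of HigA and LexA overlap, and its design text places their overlap at the higBA promoter alone. At that promoter the LexA probe with the highest value, 3281551 to 3281600, and the HigA probe with the highest value, 3281501 to 3281550, were 50 bp apart. The LexA probe lay 51 bp upstream of the higB start, between higB and the divergent gene CCNA_03134, and the HigA probe 1 bp upstream. The listed probes on either side had lower values in both libraries. The lists with genes hold 1 probe per gene, and neither library had a listed value at the highest probe of the other. The 50 bp therefore need not be the distance between the true peaks. HigA gave 0.0125% at 3281351 to 3281400 and 0.0120% at 3281651 to 3281700, where LexA gave 0.0627% and 0.0766%.

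**Figure D2:**
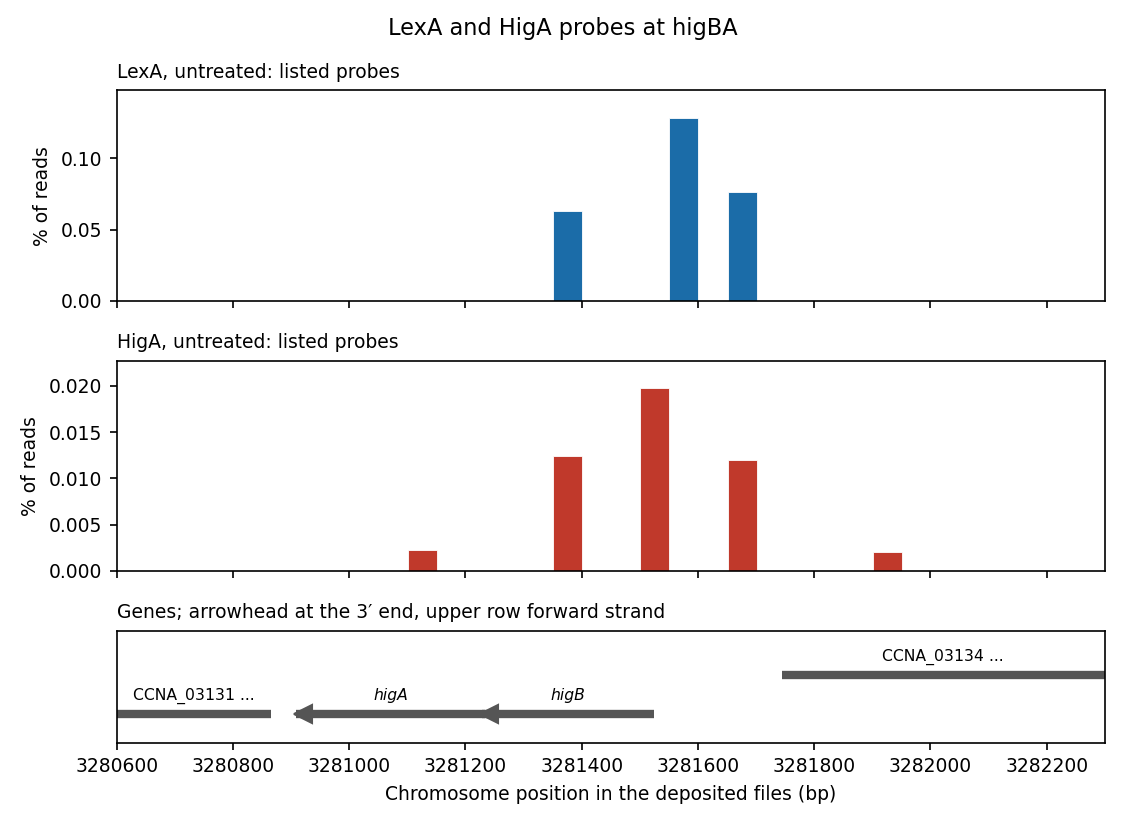
Percent of reads in each listed probe (bars, 50 bp wide, each axis from 0) for LexA and HigA against chromosome position in bp, with the genes from the deposited lists below. The highest LexA bar, 0.128%, and the highest HigA bar, 0.0198%, lie 50 bp apart at the start of higB; unlisted probes are blank.

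Over the full lists 5 regions were shared, counted after widening each by 100 bp. At the other 4 the HigA value was within 1.27 times the lowest of its list. HigA stood at 0.00197% in the region of chlI, whose highest probe was listed without a gene. It stood at 0.00237% in the region of ruvA, ruvC and CCNA_03347, whose highest probe was listed for CCNA_03347. At CCNA_03633 it was 0.00188% and at CCNA_03820 0.00191%. In that order these were 1.06, 1.27, 1.01 and 1.02 times its lowest value. Their ranks were 209, 27, 381 and 317 of 443, where tied regions take the best rank of the tie. LexA at CCNA_03820 was 0.0284%. Among 10000 circular shifts the mean was 3.39 shared regions and the central 95% ran from 0 to 8, so that 5 lay inside the range of the shifts. With regions at or above 1.5 times the lowest value of each list, 1 was shared, higBA, and 7.23% of circular shifts gave at least 1.

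TipR without drug was highest at its own gene. The list held 11 probes in 8 regions, from 0.00472% to 0.124%. The highest probe, at 927551 to 927600, lay 63 bp upstream of tipR (CCNA_00852), next to the divergent gene CCNA_00851, which had 0.115%, and reached 50.5 times the library mean implied by the score. CCNA_02218 had 0.0449% and its neighbour CCNA_02219 0.0338%. A region at the facing 3′ ends of qor and rho, the transcription termination factor gene, had 0.0391%, and ccrM, the gene of the cell cycle DNA methyltransferase, 0.0362% at a probe 62 bp upstream. CCNA_01125 had 0.00870%, CCNA_02719 0.00556%, and regions with no gene at 928301 and 1758451 had 0.00543% and 0.00472%.

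After nalidixic acid the same antibody gave lower values at the sites listed in both conditions and a longer list. It held 683 probes in 657 regions, from 0.00599% to 0.0157%, and 96.0% of these regions were lone probes. Of the 8 untreated regions 5 met a region of this list, against a mean of 0.682 and a central 95% of 0 to 2 in circular shifts. At tipR the value was 0.124% without and 0.0129% with the drug, a ratio of 9.57. The ratio was 5.40 at ccrM (0.00670% with the drug), and at tipR and ccrM the same probe was highest in both conditions. The ratio was 4.06 at CCNA_02218 and CCNA_02219 (0.0111%), 3.39 at qor and rho (0.0115%) and 1.43 at CCNA_01125 (0.00609%). There the highest probes of the conditions lay 50, 100 and 150 bp apart, in that order. At the qor and rho probe listed in both conditions the ratio was 3.49. The remaining 3 untreated regions had values under the lowest value listed after the drug, so their absence from that list carries no comparison.

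**Figure D3:**
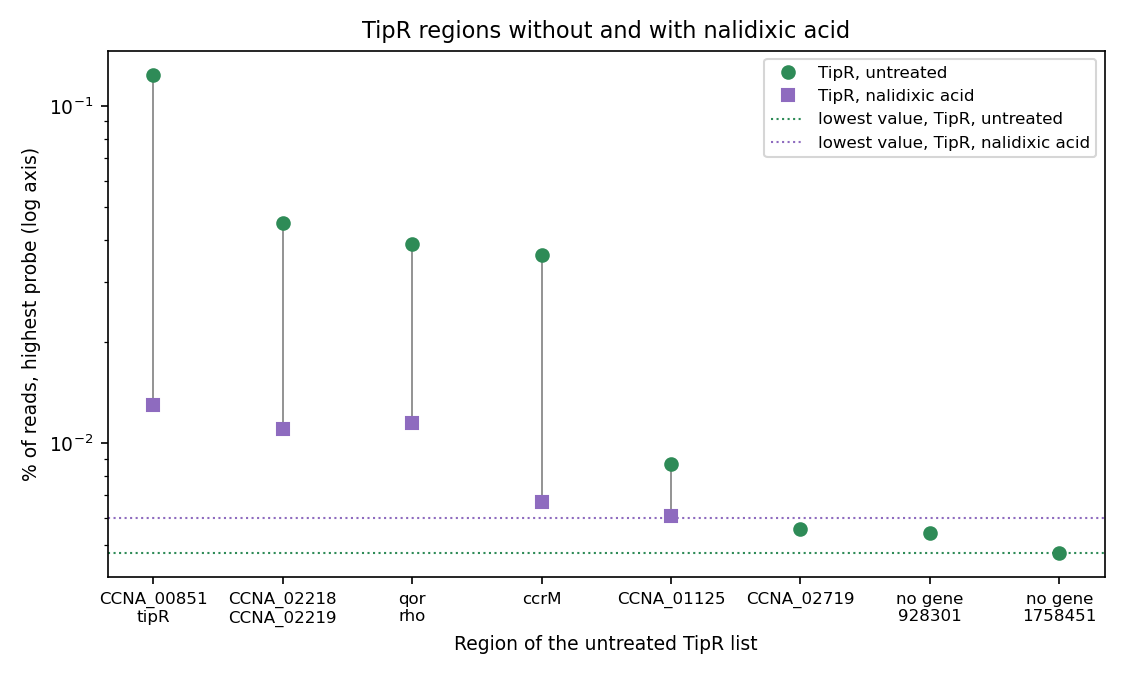
Percent of reads at the highest probe (log axis) of the 8 regions of the untreated TipR list, without drug (circles) and, where listed, with nalidixic acid (squares); dotted lines are the lowest listed values. The 5 regions in both lists have higher values without the drug, from 1.43 times at CCNA_01125 to 9.57 times at tipR.

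In the library with nalidixic acid the tipR region ranked 27 of 657. The highest regions had no gene, led by 112651 to 112700 at 0.0157%, 393001 at 0.0153% and 3928651 at 0.0153%. The highest with a gene was acrB5, of a drug efflux transporter family, at 0.0151% and 270 bp upstream, ahead of CCNA_00402 at 0.0145% and CCNA_02920 at 0.0143%. The other regions of the 12 highest had no gene and lay between 0.0139% and 0.0151%. Of the 4 efflux list members tipR and acrB (0.0132%) were listed, as many as in 1.62% of the rotations, and in the untreated TipR list tipR alone (0.901% of rotations). The efflux list holds tipR, the gene of the precipitated protein and the site of the highest untreated value, so the untreated share restates that site and the share with the drug rests on it in part. The SOS and DNA repair list had 2 members with the drug, ruvB at 0.0105% and mutY at 0.00648% (37.3% of rotations), and the toxin-antitoxin list 0.

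LexA probes lay closer to gene starts than those of the long lists. The median upstream distance of probes listed with a gene was 38.5 bp for LexA, 55 bp for untreated TipR, 205 bp for HigA and 199 bp for TipR with nalidixic acid. The untreated TipR median is over the 7 of 9 probes with a deposited distance. The authors gave none for qor and rho, whose probes lay at the 3′ ends, and the median with their recomputed distances was 48 bp. A peak probe between 300 bp upstream and 100 bp downstream of a gene start was found in 43 of 47 LexA regions (91.5%, exact 95% interval 79.6 to 97.6), 5 of 8 TipR regions (62.5%, 24.5 to 91.5), 111 of 443 HigA regions (25.1%, 21.1 to 29.4) and 127 of 657 TipR regions with the drug (19.3%, 16.4 to 22.6). The LexA list was by gene by construction, so each of its 47 regions held a gene. A gene was listed in 173 of 443 HigA regions, 6 of 8 TipR regions and 202 of 657 TipR regions with the drug. Peaks without a listed gene could not count, so the shares are not like for like across lists. The intervals cover counting error only.

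Regions met by unrelated antibodies were counted as a background of the method. TipR without the drug shared 1 region with LexA, CCNA_01125, where TipR had 0.00870% and LexA 0.317% at probes 50 bp apart, and 2 with HigA. Both counts were above the circular shift means of 0.0523 and 0.547, and 5.06% and 9.50% of the circular shifts gave as many. Of local shifts by 2 to 30 kb, 2.93% and 8.15% did. TipR with the drug shared 3 regions with LexA and 35 with HigA, below the circular shift means of 4.36 and 44.1, and 81.6% and 66.5% of the shifts gave as many. Of local shifts 87.4% gave as many for LexA and 100% for HigA, where the local mean was 60.5. No control library was used here.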

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

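There were 110 alternative values for 34 results, 102 planned and 8 chosen after seeing the data, and 61 stayed within limits while 49 moved; the cause was not tested beyond what each setting removes by construction. Not run were the SOS box search with its alternatives and gene assignment from a reference annotation. No paired analysis was possible because each group had 1 library. No read totals were given or derived, so values near a list's end carry no counting error here, which limits their reading.

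At 1.5 times the lowest value the regions fell from 443 to 9 for HigA, from 8 to 5 for TipR and from 657 to 212 for TipR with the drug. At 2 times, chosen after seeing the data, they were 6, 4 and 52. With the upper 50% by value they were 23 for LexA, 221 for HigA, 4 for TipR and 328 for TipR with the drug. At the lowest LexA score, also chosen after, TipR had 4 regions without and 0 with the drug.

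LexA and HigA shared 5 regions as deposited, 1 at 1.5 times and 1 at 2 times the lowest value, 3 in the upper 50%, 8 with only touching probes joined, 2 without widening and 10 with widening by 500 bp. Counted as genes they shared 9, which are the genes of the same 5 regions. The TipR libraries shared 5, and 3 both at 1.5 times the lowest value and in the upper 50%. TipR and LexA shared 1, and 0 in the upper 50% or without widening. TipR and HigA shared 2, and 0 at 1.5 times, 1 in the upper 50%, 0 without widening, 4 with 500 bp and 1 counted as genes. TipR with the drug and LexA shared 3, and 0 at 1.5 times, 0 in the upper 50%, 0 without widening, 16 with 500 bp and 1 counted as genes. With HigA it shared 35, and 0 at 1.5 times, 10 in the upper 50%, 6 without widening, 140 with 500 bp and 14 counted as genes.

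The share of LexA regions at gene starts was 91.5%, and 100% in the upper 50% or with the window of 500 bp upstream to 200 bp downstream. The 100% with that window was fixed by the list, which held only probes with a gene start inside it. For HigA it was 25.1%, and 44.4% at 1.5 times the lowest value, 11.1% with 150 bp upstream to 50 bp downstream and 33.6% with the wide window. For TipR with the drug it was 19.3%, and 15.1%, 8.22% and 29.1% in the same order. In these long lists distances were had only for probes listed with a gene, and none exceeded 399 bp upstream or 99 bp downstream. The wide window could therefore not reach its named limits, and its shares do not count peaks farther from a gene start. LexA toxin-antitoxin genes of the fixed list were 9, and 3 in the upper 50% by value, which leaves out weaker regions by construction.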

Other observations

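Most tests in this part were chosen after the result was seen: those on the HigA positions and distances, on the TipR probes and ratios, on the acrB family, on COG letters and on the 5 shared regions. The threshold of 1.5 times the lowest value was planned, and the higBA count test was written before its own value was seen. The test on the strongest HigA region was added after that count test had come out, and the TipR subsets by peak distance were picked after their values were seen.

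By the COG letter in the deposited lists, replication, recombination and repair took 12 of the 50 LexA genes with a COG entry. That is 24% (exact 95% interval 13.1 to 38.2). The 12 include recA, ruvA, ruvC and uvrD of the SOS list. Entries without a letter, as for imuA and mmcB, stayed among the 50 and were not counted as repair genes. The share was 4 of 166 for HigA (2.41%, 0.660 to 6.05) and 9 of 161 for TipR with nalidixic acid (5.59%, 2.59 to 10.3), and 1 of 4 for untreated TipR (25%, 0.631 to 80.6), too few genes to compare. Another toxin-antitoxin pair outside the fixed list, relB-4 at 0.0822% and relE4 at 0.0438%, was chosen after its values were seen.

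After nalidixic acid 3 of 5 acrB family genes, which encode drug efflux transporters, were in the TipR list: acrB5 at 0.0151%, acrB at 0.0132% and acrB4 at 0.00653%, 248 to 320 bp upstream of the gene starts. The untreated TipR list, with 9 genes, had 0. The family was matched by symbol, so genes without a symbol, CCNA_00851 beside tipR among them, could not count. The 0 therefore does not show that efflux genes were absent from the untreated list. As many as 3 were found in 0.0772% of rotations of the gene order. The family was picked from this list, so that share does not bear on whether the listed genes fell there by chance, which stays open. Of the acrB family genes, acrB4 stood near the lowest listed value, 0.00599%. The untreated list already held tipR, of the efflux list, at 0.124%, so efflux list members were not confined to the drug. The divergent neighbour of tipR, CCNA_00851, had 0.115% without and 0.0125% with the drug. Binding of TipR at acrB family genes under the drug may be a hypothesis for a replicated library with a control. Pile-up of reads, weighed below for the whole list, stays open for the acrB family probes too.

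The HigA regions lay near the ends of the chromosome coordinates, with 415 of 443 (93.7%) within 25% of the coordinate span of either end, against 25 of 47 for LexA (53.2%) and 4 of 8 for untreated TipR. TipR with nalidixic acid also leaned that way, with 460 of 657 (70.0%, 66.4 to 73.5), 81.6% of its regions at or above 1.5 times the lowest value and 64.5% of those below. Of the HigA regions under 1.5 times the lowest value 94.0% lay there (exact 95% interval 91.3 to 96.0). The replication origin was assumed to lie at the ends of the coordinates, which was not checked here. On that assumption, more DNA copies near the origin of growing cells may give such a pattern. Binding at gene starts was tested on the 194 weak probes listed with a gene. Their median upstream distance was 205 bp (bootstrap 95% interval 154 to 245 bp), although the lists allow up to 399 bp. The set as a whole thus did not centre on gene starts. A median cannot exclude such binding for a part of it, and 76 of all 203 HigA probes with a gene lay within 100 bp of a start. The 970 probes without a gene were not in that test. No input library was used here to separate copy number from binding, and 7 of the 9 stronger HigA regions also lay in that part.

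The TipR signal was lower and the list longer after nalidixic acid. Of the probes listed without a gene with the drug 0.418% had a listed neighbour 50 bp away, against 79.9% for HigA, which is consistent with reads piled on single probes, though a different selection by the authors may give the same. A loss of enrichment over the whole library would lower the excess over the library mean by similar ratios. Over all 5 shared sites the highest of these ratios was 6.73 times the lowest. It was 2.86 times over the 4 sites with peaks within 100 bp and 2.35 times over the 3 within 50 bp. With 1 library each the spread of the ratios is unknown, so a library-wide loss and a change in TipR binding cannot be told apart.

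The 5 regions shared by LexA and HigA were matched by 17.9% of local shifts, so coincidence with the long HigA list may account for their number. The test of higBA went the same way. At 1.5 times the lowest values, at least 1 shared region was given by 9.44% of local and 7.23% of circular shifts, so the count alone does not exclude coincidence. The strongest HigA region by itself met a LexA region in 1.51% of its shifts around the chromosome. As that test was chosen after the other and on the region that shows the pattern, the question stays open from these counts.

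TipR with the drug shared 35 regions with HigA, fewer than in any of the 10000 local shifts, whose mean was 60.5 and central 95% 47 to 73. The local shifts were added after the lists had been examined. In the planned circular shifts the mean was 44.1 and the central 95% ran from 19 to 70, so that 35 lay inside that range. The count also moved with the width, from 6 without widening to 140 with 500 bp.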
